A study of Drosophila melanogaster with 6 samples.

How the data were processed

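RNA from larval carcasses of 3 wild-type and 3 Nxt1 mutant samples was made into libraries with Illumina's stranded TruSeq mRNA kit, which selects poly(A) RNA, per the labels' protocols. Per the submitters' processing notes, reads were processed with TopHat2 2.1.1, Bowtie 1.1.1, Cufflinks and Cuffdiff on the BDGP6 build; versions of the last 2 tools are not given in the sources used here. The labels do not say whether the samples of a genotype came from separate cultures, so the authors' p-values may measure technical spread only.

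The expression table holds FPKM (fragment number scaled to transcript length and library size) that the authors pooled over the 3 samples of each genotype, with a p-value and q-value per locus, per the file headers. The splicing table holds a score deposited by the authors, the square root of the Jensen-Shannon divergence between genotypes, with its p-value and q-value. The other deposited tables give intron lengths, intron numbers and transcript lengths of genes in classes that the authors formed by fold change. No values per sample were analysed here. So depth, spread between samples and counting intervals are unknown, no replicate could be left out, and no count model was used. An FPKM of 0 may be a failed estimate and is written as listed at 0, with no fold. In list medians and their percentiles such loci counted as the highest or lowest values.

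Of 16702 loci, 8920 had been tested, 7781 had not been tested because of too few reads and 1 had been set aside by the authors' software. Benjamini-Hochberg values recomputed on the deposited p-values over tested loci differed from the deposited q-values by at most 5.19e-07. The deposited log2 fold change column held cells damaged by a spreadsheet and was not used; log2 ratios were computed from the 2 pooled FPKM values without a pseudocount. Of the tested loci, 8284 carried 1 gene symbol, 545 several and 91 none. A locus with several symbols has 1 value for all of them and was counted once in each list that names any of them. Locus starts in the table count from 0 and are given here from 1: so written, 69.3% of matched loci began at the annotated gene start. Of the loci with 1 symbol, 8255 were matched by symbol or synonym and by overlapping position to the Ensembl annotation release 115 of the BDGP6.54 assembly, which gave transcript and intron lengths.

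Calls used q-values under 0.05. Named genes followed a rule fixed before the data were examined: Nxt1 and tn; the 12 largest decreases and 12 largest increases among called loci with FPKM of at least 1 in both genotypes; up to 4 called members of each list by lowest q-value and then largest change, with the most abundant member; the 10 splicing calls with the largest score; and the 3 longest introns of the lower and of the higher class. The 35 lists were written before the data were examined; those of tissues other than muscle and epidermis are markers of cells the carcass could hold. The larval cuticle protein list was built on name patterns of cuticle gene families, not on the stage at which they are expressed. It also took in Cpr, a P450 reductase gene, through its name pattern. The antimicrobial peptide list also names PGRP-S recognition protein genes and Tot stress genes, and the sarcomere and muscle list also names Gapdh1 and Gapdh2. List calls were tested with Fisher's exact test against all other tested loci. Each list's median was also ranked among 10000 random lists matched on mean FPKM in 10 bins. Random lists were drawn without leaving out the list's own members or those of other lists. A large list of abundant loci is therefore partly compared with itself. Rankings matched on transcript length or largest intron used only protein-coding members with an annotated length.

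Intron lengths of classes were compared with permutation tests of the difference in median log10 length (100000 resamples; 10000 for alternatives and 2000 for matched classes). One list entry had no number for its largest intron and was left out. The authors' lists were joined to expression by gene identifier for correlations. In that join, 1592 of 1597 genes of the lower class, 1159 of 1159 of the higher class and 8 of 4124 of the non-changed class were called, so a few genes sit in a class that their joined locus does not share. Repeated gene entries across the 3 classes numbered 15. Intervals of medians and of rho are percentiles of 1000 bootstrap draws over genes.

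Alternatives fixed beforehand were other q-value thresholds, FPKM minimums, fold minimums, pseudocounts, centring, fold classes, intron measures, matching on expression and annotated lengths. Added after seeing the data were rescaling to equal FPKM sums, centring on loci with mean FPKM of at least 10, loci with 1 symbol, leaving out loci of several lists, matching on transcript length or largest intron, and partial correlations. The statistics were tested on simulated data. For lists, independent noise and random lists of 20 loci matched on expression were used, on 8877 loci. With a shift of 1 log2, 94 of 100 lists fell outside the central 95% of random lists, against 7 of 100 without a shift. Lists of other sizes, members that vary together and matching on transcript length or largest intron were not simulated. For the class comparison, 100 of 100 simulated differences of 0.5 log10 passed 0.05, against 4 of 100 without one, on 700 values each. For the partial correlation, a simulated relation running only through another variable, known without error, gave -0.00739 on 8877 loci. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.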

Results

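RNA was sequenced from the body wall of Drosophila melanogaster larvae in 2 genotypes, with 3 samples each. Late third-instar larvae that had stopped moving were opened and their internal organs removed, so the carcass is mostly body-wall muscle and epidermis with its cuticle. The wild-type larvae were w1118, a white-eyed laboratory strain. The mutant larvae carried 2 different alleles of Nxt1, the small partner of the mRNA export receptor encoded by sbr, and were labelled with a yw background. Genotype and strain background therefore changed together and cannot be separated in these samples. Expression is given as 1 FPKM value per genotype and locus, pooled by the authors over the 3 samples, so no spread between samples can be shown and the sequencing depth is unknown. A locus is called changed where its q-value in the authors' deposited table is under 0.05. Folds are ratios of the 2 pooled FPKM values, and coordinates are on BDGP6.

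The first question was how Nxt1 and tn, a muscle gene known from work on this mutant, were expressed. Nxt1 (FBgn0028411, chromosome 2R, 23809236 to 23811974) was at 44.2 FPKM in wild type and 50.4 FPKM in the mutants, with a q-value of 0.637 in the authors' deposited table. The labels do not say whether either allele lowers the Nxt1 transcript, so this level does not check the genotype labels. The gene tn (2R, 18987000 to 19009031) encodes the muscle protein thin. It was at 296 FPKM in wild type and 306 FPKM in the mutants, with a q-value of 0.899 in the authors' deposited table. The strain marker gene w, in a locus shared with CG32795, was at 17.8 and 21.5 FPKM and was not called.

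Across the transcriptome, 3599 of 8920 tested loci were called in the authors' deposited table, 1945 lower and 1654 higher in the mutants. Among loci with FPKM of at least 10 in a genotype the balance was the opposite, with 759 lower and 1423 higher. At least 4-fold changes made up 602 of the lower calls and 136 of the higher calls, and the median fold was 2.76 among lower calls and 1.89 among higher calls. The gene how (3R, 22042191 to 22079321), which encodes an RNA-binding protein needed in muscle and tendon cells, fell 20.1-fold, from 20.4 to 1.02 FPKM. Paip2, a translational repressor, fell 19.2-fold, and Bsg, the cell-surface protein basigin, fell 18.0-fold. The Hox gene abd-A fell 14.2-fold, the oxidative stress regulator cnc 11.2-fold and rin 10.4-fold. CG11893, CG17374 and the shared locus of CG43675 and CG45050 fell 18.8-fold, 14.2-fold and 11.5-fold. These were ranked among called loci with FPKM of at least 1 in both genotypes. The remaining places among the 12 largest decreases were taken by tmod, described with the muscle genes, and by 2 loci without a gene symbol on unplaced scaffolds. Cyp6a17 and CrebA, under 1 FPKM in the mutants and so not ranked, fell 36.4-fold and 30.7-fold.

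Increases were ranked among called loci with the same minimum of 1 FPKM in both genotypes. The largest was that of Cpr67Fa2 (3L, 10891714 to 10892516), a cuticle protein gene, from 10.4 to 1867 FPKM in the authors' deposited table. The locus shared by Arc1, a capsid-forming neuronal gene, and CR10102 rose 59.0-fold, from 123 to 7240 FPKM. The shared locus of the antimicrobial peptide genes CecA1 and CecA2 rose 20.8-fold, and the glutathione transferase genes GstE3 and GstO3 rose 18.0-fold and 17.4-fold. A second cuticle gene, Cpr97Ea, rose 20.9-fold. The less studied loci CG6074, CR32745, CG17105, CG7606, CR44215 and CG9686 rose between 15.6-fold and 25.3-fold.

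The balance between higher and lower loci depends on the scale. The FPKM values summed to 883018 in wild type and 1359067 in the mutants. Rescaling both genotypes to the same sum lowered every log2 fold change by 0.62, and centring on loci with a mean FPKM of at least 10 lowered it by 0.36. Among tested loci that differed at least 1.5-fold, 47.2% were higher on the authors' scale, 23.4% after that centring and 11.8% after rescaling. Of the 3599 called loci, 1945 stayed lower and 1654 higher after that centring, and 2148 were lower after rescaling. These counts give signs only, since no locus was tested again on the new scales. Among the called loci named here, only His3.3B changed direction, under rescaling. A p-value of 5e-05, the smallest in the authors' deposited table, was shared by 1672 loci, so ranks among these carry no information.

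Of 35 gene lists fixed before the data were examined, 8 held more lower calls and 8 more higher calls than the other tested loci (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 70 tests). Genes within a list are not independent, and these tests describe these libraries. Sarcomere and muscle genes went both ways. Of 42 tested loci of this list, 16 were called higher and 12 lower in the authors' deposited table, and the higher calls were enriched (exact adjusted p = 0.00965). The list also holds the glycolysis genes Gapdh1 and Gapdh2, both called higher. With loci of more than 1 list left out, 14 loci were higher (exact adjusted p = 0.0409). Mlp60A, a muscle LIM protein gene, rose from 591 to 6614 FPKM, and Mp20, a calponin-like muscle protein gene, from 1140 to 6642 FPKM. The actin-capping gene tmod (3R, 30532607 to 30578905) fell from 98.6 to 9.20 FPKM, and the locus holding the calmodulin gene Cam from 104 to 16.5 FPKM. The list's median log2 fold change of 0.19 turned to -0.17 after centring on loci with mean FPKM of at least 10 and to -0.43 after rescaling. The median of 0.19 lay at percentile 2.78 of random lists matched on expression. Over the 37 loci with an annotated length the median was 0.28. That value lay at percentile 97.0 of lists also matched on transcript length and at 93.6 of those also matched on the largest intron. The percentiles therefore differ in the loci covered as well as in the matching.

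The list of regulators of muscle identity and RNA processing held more lower calls than other loci. Of 13 tested loci, 8 were called lower and none higher in the authors' deposited table (exact adjusted p = 0.00965 for lower calls), with a median log2 fold change of -2.61. With a pseudocount of 1 FPKM the median was -0.74. Besides how, the homeobox gene hth fell 19.2-fold, the splicing factor gene A2bp1 15.4-fold, from 1.6 to 0.104 FPKM, and the flight-muscle selector salm 14.1-fold, from 0.978 to 0.0693 FPKM. The locus with the myogenic factor gene Mef2 was at 77.9 and 46.2 FPKM and was not called. With loci under 1 FPKM in both genotypes left out, 5 lower calls remained and the adjusted p was 0.0512 by Fisher's exact test.

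The lists of circular RNA host genes and of heterochromatic genes with very large introns also held more lower calls. Of 12 tested host loci, 10 were called lower (exact adjusted p = 7.89e-05), and of 6 heterochromatic loci, 5 were (exact adjusted p = 0.00965). Among the hosts, the splicing regulator mbl fell 11.2-fold, from 0.676 to 0.0605 FPKM, laccase2 8.14-fold, PlexA 7.41-fold and pan 6.36-fold. Among the heterochromatic genes, uex fell 8.41-fold, cta 4.58-fold, Dbp80 2.95-fold and the MAP kinase gene rl 1.78-fold. Against random lists matched on expression and the largest intron, the median of the hosts lay at percentile 3.2 and that of the heterochromatic genes at 27.6, both inside the central 95%. Circular RNAs themselves were not analysed here.

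Extracellular matrix genes fell, with 13 of 16 tested loci called lower and 1 higher in the authors' deposited table (exact adjusted p = 6.1e-06 for lower calls). LanA, a laminin chain gene, fell 4.75-fold, Ppn 3.52-fold and the collagen gene Mp 2.87-fold. The laminin gene wb fell 4.27-fold, from 0.564 to 0.132 FPKM. The list lay at percentile 6.45 of random lists matched on transcript length and expression. It shared 4 of its loci with the hemocyte markers, of which 7 of 16 were lower, and Mmp1 with the tracheal markers, of which 5 of 7 were lower; with loci of more than 1 list left out, 9 of 11 loci were lower (exact adjusted p = 0.000297). In the chitin and cuticle modification list, 13 of 25 loci were lower and 5 higher (exact adjusted p = 0.00437 for lower calls). The tyrosine hydroxylase gene ple fell from 1426 to 188 FPKM, whereas Ddc, the next enzyme of dopamine synthesis, rose from 1567 to 4246 FPKM. Cda5, a chitin deacetylase gene, fell 8.06-fold, from 0.879 to 0.109 FPKM, and obst-E, a chitin-binding protein gene, rose 4.92-fold. The genes of the larval cuticle protein list, chosen by name pattern and not by stage, did not pass as a group. Of 66 loci, 17 were higher and 8 lower (exact adjusted p = 0.329 and 0.191). Their median log2 fold change of 0.18 over loci with an annotated length lay at percentile 0.045 of random lists matched on transcript length, whose median was 0.58. It lay at percentile 45.5 of lists matched on the largest intron. Over all 66 loci the median of 0.16 lay at percentile 78.9 of lists matched on expression alone. TwdlO rose 52.2-fold, TwdlK was listed at 0 in wild type and 3.70 FPKM in the mutants, and Lcp4 was at 64322 and 62628 FPKM.

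Ecdysone response genes fell, with 13 of 21 tested loci called lower and 2 higher in the authors' deposited table (exact adjusted p = 0.000484 for lower calls). The ecdysone receptor gene EcR (2R, 6087873 to 6169087) fell from 24.5 to 2.88 FPKM, the nuclear receptor gene Hr4 fell 6.45-fold and ImpE2 5.33-fold. Blimp-1, under 1 FPKM in both genotypes, fell 19.9-fold, from 0.902 to 0.0454 FPKM. ImpL3, which encodes lactate dehydrogenase, rose 3.04-fold. Of 5 tested ecdysone synthesis loci, sad rose from 6.05 to 12.7 FPKM and Cyp18a1, which inactivates the hormone, fell 2.27-fold. In the insulin, FOXO and starvation list, 7 of 13 loci were lower and 1 higher (exact adjusted p = 0.038 for lower calls). Among them chico fell 13.3-fold, foxo 4.27-fold, the insulin-binding protein gene ImpL2 4.08-fold and the lipase gene bmm 3.33-fold. This list did not pass at a q-value under 0.01 (exact adjusted p = 0.053) or without loci shared with other lists (exact adjusted p = 0.138).

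Lists of translation, protein breakdown and energy metabolism held more higher calls. Of 86 cytoplasmic ribosomal protein loci, 66 were higher and 1 lower in the authors' deposited table (exact adjusted p = 4.48e-30), and 38 of 73 mitochondrial ribosomal protein loci were higher and none lower (exact adjusted p = 3.45e-09). RpL36 rose 2.41-fold and mRpL27 rose 2.54-fold. Of 33 proteasome loci, 22 were higher (exact adjusted p = 3.85e-08), among them Prosbeta3, up 2.31-fold. Of 17 oxidative phosphorylation loci, 13 were higher (exact adjusted p = 3.87e-06), among them levy, up 2.47-fold. Of 13 glycolysis loci, 11 were higher and 1 lower (exact adjusted p = 4.67e-06). Pglym78 rose 3.51-fold, Gapdh1 3.41-fold, Tpi 3.36-fold and Gapdh2 3.10-fold. After rescaling to equal sums the medians of these lists were 0.30, 0.15, 0.18, 0.18 and 0.80 on the log2 scale. Against random lists matched on expression, the proteasome median lay at percentile 85.8 and that of oxidative phosphorylation at 89.5, within the range of equally abundant loci. The other 3 lay at percentile 100, of which the mitochondrial ribosomal proteins came to 94.3 with matching on transcript length as well.

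The antimicrobial peptide list also names PGRP-S and Tot genes. Of its 28 tested loci, 15 were called higher and 1 lower in the authors' deposited table (exact adjusted p = 0.000206), with a median log2 fold change of 1.62. AttD rose 11.7-fold, IM1 8.49-fold and DptB 7.47-fold, and the most abundant member, Drsl5, rose from 5633 to 13846 FPKM. Of 59 glutathione and P450 detoxification loci, 25 were higher and 3 lower (exact adjusted p = 0.000169), with a median of 0.67 that came to 0.04 after rescaling and 0.43 with a pseudocount of 1 FPKM. Cyp9c1 rose 8.57-fold and GstD1 1.70-fold, whereas Cyp6a17 fell from 13.8 to 0.38 FPKM. Midgut markers, described below with the other tissues, had a median log2 fold change of 0.90 beside these 2 lists. The Cyp6a, cecropin and Hsp70 genes have near-identical neighbours, so reads may be divided among them. Heat shock genes did not pass as a group, with 7 of 23 loci higher and 7 lower. The small heat shock genes l(2)efl and Hsp26 rose 5.52-fold and 3.31-fold, and Hsp70Bc and Hsp70Bb fell 16.1-fold and 13.2-fold.

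**Figure D1:**
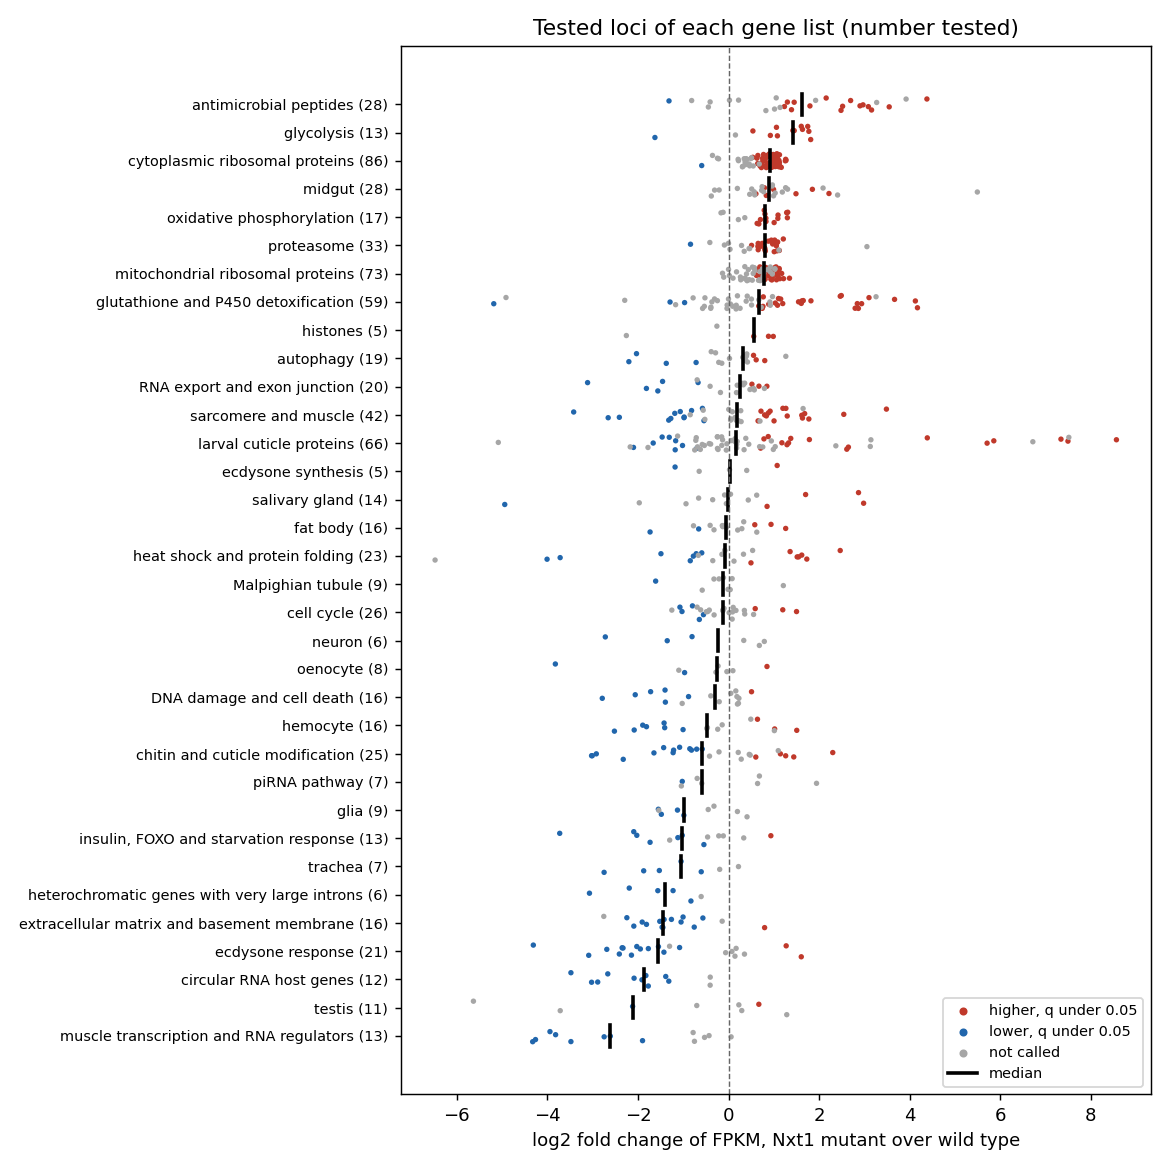
Log2 fold change of pooled FPKM, Nxt1 mutants over wild type, for each tested locus of the gene lists with at least 5 tested loci. Each point is a locus, red where called higher, blue where called lower and grey otherwise. Black bars are list medians, from 1.62 for antimicrobial peptides to -2.61 for muscle regulators (-0.74 with a pseudocount of 1 FPKM). Loci listed at 0 in 1 genotype are not drawn but count in the medians as the highest or lowest values.

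Marker genes of other tissues moved in both directions. Of 7 tracheal loci, 5 were lower and none higher in the authors' deposited table (exact adjusted p = 0.0242), among them tyn, down 6.72-fold. The tracheal list did not pass at a q-value under 0.01 (exact adjusted p = 0.0652) or without loci shared with other lists, here Mmp1 (exact adjusted p = 0.0763), and it lay at percentile 26.9 of random lists matched on transcript length and at 20.045 of those matched on the largest intron. Hemocyte markers had 7 of 16 loci lower and 3 higher, with eater down 5.74-fold and Sr-CI down 4.24-fold. As a group they did not pass at a q-value under 0.05 (exact adjusted p = 0.17 for lower calls). They did at a q-value under 0.01 and with loci of 1 symbol only (exact adjusted p = 0.0469 and 0.0363). Glial markers had 4 of 9 loci lower and neuronal markers 3 of 6, among them Gs2, down 2.19-fold, and Csp, down 1.75-fold, and neither list passed (exact adjusted p = 0.288 and 0.306 for lower calls). The median of the 6 neuronal loci was -0.24, at percentile 58.4 of random lists matched on expression. Over the 5 with an annotated length, which leave out the lower locus of 4EHP and Syx1A, it was 0.33. That value lay at percentile 99.9 of random lists matched on transcript length, whose median was -1.46, and at 96.8 of those matched on the largest intron. Midgut markers had 7 of 28 loci higher and none lower, fewer lower calls than other loci (exact adjusted p = 0.00901), while their higher calls were not enriched (exact adjusted p = 0.578). Their median log2 fold change of 0.90, which was 0.58 with a pseudocount of 1 FPKM and 0.27 after rescaling, lay at percentile 100 of random lists matched on expression and at 98.8 of those also matched on transcript length. The trypsin gene alphaTry was at 2.6 and 7.27 FPKM, and the most abundant member, Npc2b, at 68.3 and 118 FPKM. Of 14 salivary gland loci, 4 were higher, including Sgs8, from 12.4 to 98.1 FPKM, and 1 was lower, CrebA, from 2.42 to 0.0787 FPKM. Fat body markers had 3 of 16 loci higher and 2 lower, with Obp99b up 2.39-fold. The counts of higher and lower loci were 1 and 2 of 8 for oenocytes, 0 and 1 of 9 for Malpighian tubules, and 1 and 3 of 11 for testis.

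The remaining lists passed in neither direction. Of 20 RNA export and exon junction loci, 3 were higher and 5 lower, with Nup153 down 8.66-fold, Nup358 down 3.52-fold and tho2 down 2.75-fold. Ref1, an export adaptor gene, was at 73.1 and 126 FPKM and was not called. Of 16 DNA damage and cell death loci, 6 were lower and 1 higher, among them hid, down 6.91-fold, and rpr, down 4.18-fold. Autophagy genes had 3 of 19 loci higher and 4 lower, cell cycle genes 3 and 5 of 26, histone genes 3 and 0 of 5, and piRNA pathway genes 0 and 1 of 7. In the histone list, His3.3B rose 1.47-fold on the authors' scale and lay at -0.07 on the log2 scale after rescaling. Adjusted over the list alone, 71 cytoplasmic ribosomal, 39 mitochondrial ribosomal, 25 proteasome, 16 antimicrobial, 7 chitin and 6 midgut loci were higher. In the same adjustment, 14 extracellular matrix, 13 sarcomere, 8 insulin, 8 hemocyte and 0 piRNA loci were lower, and every other count was as given.

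The authors' lists of genes by expression class allow the question whether changed genes differ in intron length. Genes lower by at least 1.5-fold had a median largest intron of 2341 nt (95% bootstrap interval 2081 to 2627, 1821 genes), against 228 nt in non-changed genes (210 to 248, 4753 genes). Genes higher by at least 1.5-fold had 160 nt (140 to 192, 1339 genes). Both differences passed a two-sided permutation test over genes, with an adjusted p of 2e-05 for the lower class, whose raw p of 1e-05 is the smallest the 100000 resamples can give, and 0.0005 for the higher class. Genes are not independent replicates. The non-changed class also holds genes that differed without a call. Of its 4124 genes joined to a tested locus, 502 were at least 1.5-fold lower and 569 at least 1.5-fold higher, and 558 had wild-type FPKM under 1. In the lower class the median was 3642 nt at 4-fold (2931 to 4788, 567 genes) and 8081 nt at 16-fold (2074 to 12605, 32 genes), an interval that includes the 1.5-fold median. The longest introns of the lower class lay in pum (132737 nt), rg (113165 nt) and jing (110416 nt). Those of the higher class lay in Bx (45656 nt), alpha-Man-Ia (44374 nt) and Glut1 (36728 nt). The translational repressor pum fell from 8.37 to 1.42 FPKM, and the glucose transporter gene Glut1 rose from 55.2 to 115 FPKM.

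Transcript length separated the same classes. The median longest transcript was 4263 nt in the lower class, 1856 nt in non-changed genes and 1186 nt in the higher class. In the lower class it was 5168 nt at 4-fold and 5761 nt at 16-fold. With genes matched on longest transcript in 10 bins, the difference in median log10 largest intron fell from 1.01 to 0.21 for the lower class. For the higher class it turned from -0.15 to 0.15 (permutation p = 0.0005 for each, the smallest that 2000 resamples give). That matching was added after the data were seen.

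**Figure D2:**
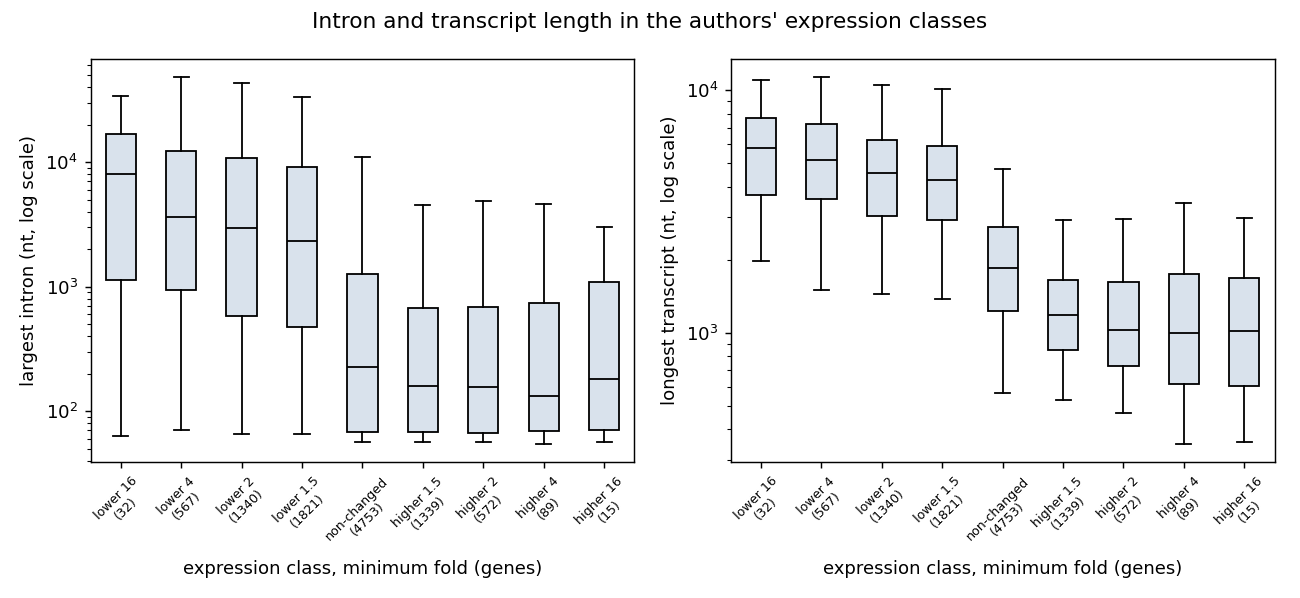
Largest intron (left) and longest transcript (right), in nt on log axes, for genes in the authors' classes by minimum fold, with gene numbers in brackets. Boxes span the quartiles with the median as a line and whiskers reach the 5th and 95th percentiles; the median largest intron is 2341 nt in the 1.5-fold lower class, 228 nt in non-changed genes and 160 nt in the 1.5-fold higher class.

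Across 6106 genes with wild-type FPKM of at least 1, the log2 fold change fell with the largest intron. Spearman's rho was -0.394 (95% bootstrap interval -0.415 to -0.372) and Pearson's r with log10 length was -0.405, each with a permutation p and an adjusted p over the pair of 1e-05, the smallest possible. Given longest transcript and wild-type FPKM, the partial rank correlation was -0.128. Over 6940 protein-coding loci the log2 fold change fell more steeply with the longest transcript (rho = -0.657). Its median was 0.71 for transcripts under 1000 nt and -1.74 for those of 6000 nt or more, where 80.6% of loci were called lower.

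**Figure D3:**
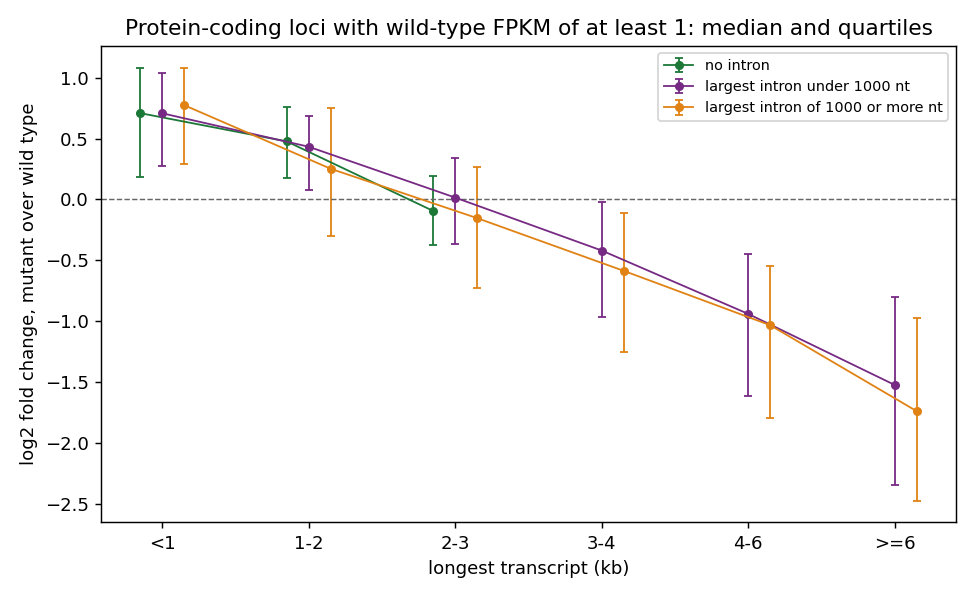
Median log2 fold change (points) with quartiles (bars), mutant over wild type, by longest transcript in kb, for protein-coding loci with wild-type FPKM of at least 1. Lines join loci without introns, with a largest intron under 1000 nt and with one of 1000 nt or more, and bins with under 20 loci are not drawn; in loci with introns under 1000 nt the median runs from 0.71 to -1.52.

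The splicing table asks whether transcripts from the same start site changed their proportions. Of 3459 start-site groups tested, 90 in 90 genes were called at a q-value under 0.05 in the authors' deposited table. The size is given as the square root of the Jensen-Shannon divergence, a distance with no direction, whose upper limit is not given in the sources used here. Its median was 0.404 in called groups and 0.0736 in the others. The largest values were those of the P450 gene Cyp9c1 (0.833), CG3714 (0.801), CG8086 (0.776), Bsg25D (0.73) and the translation factor gene eIF4G (0.725). CG32369, PH4alphaEFB, CG12018, the hypoxia regulator sima and the RNA-binding protein gene shep followed, between 0.71 and 0.72. Each of the 10 had a q-value of 0.00309 in the authors' deposited table, the smallest there. From the fixed lists, Nup153, Strn-Mlck, lt, Fbp2 and Rpn13 also had a call.

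Genes with a splicing call had expression calls more often. Of 3134 genes tested in both of the authors' deposited tables, 57 of the 90 with a splicing call also had an expression call, against 1567 with an expression call in all (odds ratio 1.75, two-sided Fisher's exact test, p = 0.0135). Of those 57 genes, 47 were lower and 10 higher, and among genes with an expression call the lower direction was more frequent in those with a splicing call (odds ratio 2.94, Fisher's exact p = 0.00119). Restricted to genes with FPKM of at least 10 in a genotype, the overlap gave an odds ratio of 1.57 and an exact p of 0.104.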

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

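Among loci that the authors did not test, 8 had an FPKM of at least 1 in the mutants and were listed at 0 in wild type. The highest were snoRNA:Me28S-C3420b at 25.1 FPKM, CR43701 at 20.2 FPKM and mir-4914 at 17.7 FPKM. In the opposite direction, 4 snoRNA loci were listed at 0 in the mutants with 1.07 to 1.73 FPKM in wild type. No test was made of these loci. Loci were left untested for too few reads, except 1 that was set aside, and a listed 0 may be a failed estimate. These values therefore do not show a difference between the genotypes.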

How the results depend on the processing

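No paired analysis was possible because the files used here give only pooled values per genotype; for the same reason no replicate was left out, no split of the samples was counted and no pseudocount per sample was tried. Depth is unknown, so how it limits these results cannot be stated. Alternatives by rescaling, by centring on abundant loci, by loci with 1 symbol, by leaving out loci of several lists, by transcript length, by largest intron and by partial correlation were chosen after seeing the data. Of 54 alternatives of the principal results, 46 kept the direction and the side of the threshold, or a count within 1.5 times. Of the rest, 2 moved, 3 weakened and 3 reversed. The 46 include recomputed Benjamini-Hochberg values, which could only return the deposited calls.

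With FPKM of at least 10 in a genotype, 759 loci were lower and 1423 higher, so the excess of lower calls turned; at 2-fold or more, 1405 were lower and 689 higher; both settings remove loci by construction. At 1.5-fold, 2268 tested loci were higher and 2537 lower; centring on loci with FPKM of at least 1 gave 1913 and 2756, centring on abundant loci 1068 and 3498, and rescaling 588 and 4385. The sarcomere median turned from 0.19 to -0.17 under centring on abundant loci and -0.43 under rescaling, and His3.3B came to -0.068 under rescaling; these follow from a constant shift. Lists lost an enrichment of lower calls in 5 cases. At a q-value under 0.01 the insulin, FOXO and starvation list had an exact adjusted p of 0.053 and the trachea list 0.0652, with loci of more than 1 list left out they had 0.138 and 0.0763, and with FPKM of at least 1 the muscle regulators had 0.0512. The hemocyte list gained one at a q-value under 0.01 and with loci of 1 symbol (exact adjusted p = 0.0469 and 0.0363). With a pseudocount of 1 the median log2 fold change moved from -2.61 to -0.74 for muscle regulators, from -1.87 to -1.13 for circular RNA hosts, from 0.67 to 0.43 for detoxification and from 0.90 to 0.58 for midgut markers. The midgut list kept fewer lower calls at a q-value under 0.01, with FPKM of at least 1 and with loci of 1 symbol (exact adjusted p = 0.0383, 0.0206 and 0.00794).

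For the smallest intron, the differences in median log10 length from non-changed genes were -0.0073 in the lower class and 0.0142 in the higher class. Matched on longest transcript, the higher class differed by 0.15; the cause was not tested beyond that matching. At 4-fold and 16-fold the higher class differed by -0.234 (permutation p = 0.128) and -0.103 (permutation p = 0.765), with 89 and 15 genes. The rank correlation with intron length ranged from -0.438 to -0.128 over its alternatives. Splicing calls numbered 61 at a q-value under 0.01 and 132 under 0.10. The odds ratio of splicing with expression calls was 1.57 with FPKM of at least 10; fewer genes were tested.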

Other observations

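Chromosome 4 stood apart. Of its 72 tested loci, 41 were called lower and 5 higher in the authors' deposited table, and their median log2 fold change was -1.56. On each of the 5 other chromosome arms named here, medians lay between -0.02 and 0.10. Among 59 protein-coding loci of chromosome 4 with an annotated length, the median was -1.83, below all of 10000 random lists matched on transcript length and expression, whose median was -0.68. This comparison was chosen after its values were seen. The pair of unnamed loci on the mitochondrial genome rose from 995 to 1643 FPKM and from 1416 to 2669 FPKM.

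The tests of the 3 patterns weighed here, matching on transcript length and on the largest intron included, were chosen after the data had been seen; only the matched values of the antimicrobial and ecdysone lists were not yet known. The first pattern is the fall of long transcripts in the mutants. Intron length alone is argued against by loci without introns, in which rho with longest transcript was -0.407 (95% bootstrap interval -0.492 to -0.329). The partial correlation of -0.128 with the largest intron cannot decide on transcript length alone, since the longest annotated transcript may differ from the one expressed. The fixed lists do not account for the pattern, since rho was -0.653 among the 6333 loci in none of them. These were most of the 6940 loci, so long gene groups outside the lists were not tested. A difference in RNA integrity or length-dependent recovery between the libraries remains a candidate explanation, since rho was -0.22 even among loci without introns under 2000 nt. A dependence of long mRNAs on Nxt1, or a strain difference, would give the same sign and was not tested.

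The second pattern is the rise of the antimicrobial peptide list, PGRP-S and Tot genes included, whose transcripts are short (median 468 nt). Short length is argued against as the whole source, since the list lay at percentile 100 of random lists matched on transcript length and expression, whose median was 0.67. Midgut markers, at a median of 0.90, lay at percentile 98.8 of the same kind of lists. Infection, a difference in remaining midgut, the strain background and the Nxt1 genotype were not tested and may each contribute.

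The third pattern is the fall of ecdysone response genes, whose median longest transcript was 5032 nt. Long transcripts and long introns are argued against as the whole source, since the list lay at percentile 0.01 of lists matched on transcript length and at percentile 0 of lists matched on the largest intron. A difference in developmental timing between the genotypes may also lower these genes and was not tested.

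Matched on expression alone, the median of the heterochromatic genes lay at percentile 1.24, trachea at 2.3 and the insulin, FOXO and starvation list at 0.42. Antimicrobial peptides, detoxification and midgut lay at 100, and the other lists with more lower calls at 0. Of the lists that passed in neither direction, glia lay at 1.29, hemocytes at 1.75, heat shock at 1.6 and testis at 0.16. The testis median of -2.12 counts loci listed at 0 in the mutants as the lowest values. With a pseudocount of 1 FPKM it was -0.52.

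Matched on transcript length and expression, over members with an annotated length, several other lists lay inside the central 95% of their random lists. The percentiles were 97.0 for sarcomere and muscle, 26.9 for trachea, 93.6 for the proteasome, 94.3 for mitochondrial ribosomal proteins, 78.1 for oxidative phosphorylation, 6.45 for the extracellular matrix, 7.41 for circular RNA hosts and 6.44 for the heterochromatic genes. Glycolysis lay at 100, cytoplasmic ribosomal proteins at 98.5, detoxification at 99.9, midgut at 98.8, the insulin, FOXO and starvation list at 0.945, muscle regulators at 0.21 and chitin and cuticle modification at 0.04. Of the lists that passed in neither direction, larval cuticle proteins lay at 0.045, testis at 0.085, hemocytes at 2.14 and neurons, over 5 loci, at 99.9. Matched on the largest intron and expression, the lists with more lower or more higher calls that lay inside the central 95% were sarcomere and muscle (93.6), circular RNA hosts (3.2), the heterochromatic genes (27.6), trachea (20.045), the insulin, FOXO and starvation list (3.41), the proteasome (92.4) and oxidative phosphorylation (91.3). Outside it among the lists without more calls in either direction were fat body (1.98), hemocytes (0.34), heat shock (0.755), testis (0.24) and midgut (100).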
